A study of Rattus norvegicus with 24 samples.

How the data were processed

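RNA was sequenced from tissue punches of 2 brain regions of adult rats, described as male in the labels, the nucleus accumbens (NAC) and the ventral tegmental area (VTA). The fathers of these rats had self-administered either morphine (MOR-sired offspring) or saline (SAL-sired offspring) for 60 days. There were 7 SAL-sired and 7 MOR-sired NAC libraries, and 5 SAL-sired and 5 MOR-sired VTA libraries. Per the labels' protocols, offspring were at least 60 days old, the punches were bilateral, RNA was extracted with an organic solvent and a column, and libraries were made from total RNA with a directional kit. The labels call the libraries biological replicates but name neither the animal nor the litter of any of them, so p-values measure the spread between these libraries. Littermates, if any, could not be accounted for, and it is not given whether NAC and VTA punches came from the same animals.

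The deposited values are estimated counts per gene in 2 tables, one per region. Per the submitters' processing notes, reads were handled with Trim Galore and kallisto, and DESeq2 was used, with no versions. Per the file names, the authors scaled the transcript abundances (TPM) of each library to the total of that library. Such estimated counts carry no correction between libraries, and they are not numbers of reads per gene: a short transcript receives a larger value per read than a long one, so small RNAs and their share of a library are inflated. The genome build, the annotation, the strand setting and the step from transcripts to genes are not given in the sources used here, so no coordinates are printed. Each table holds 37403 identifiers, all of which matched a gene symbol of the RefSeq annotation of assembly GRCr8. Of these, 15427 were LOC identifiers and 34 were RGD identifiers, which were tested and counted but not named. The RefSeq table was used only for names and gene classes. The mitochondrially encoded genes of a list fixed for this work were not among the identifiers, and the list was not analysed here.

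The estimated counts were rounded to whole numbers. Library totals ran from 21.9 to 41.3 M in NAC and from 23.6 to 43.5 M in VTA (1 M is 1e6 counts). Because the values are scaled estimates, no counting interval was computed for single genes. In each region separately, genes were kept by edgeR's filterByExpr and tested with edgeR's quasi-likelihood test, with TMM factors, a design of intercept and sire group, and Benjamini-Hochberg adjustment over the genes kept. A gene was called at an adjusted p under 0.05, and all tests were two-sided. A positive log2 fold change means higher in MOR-sired libraries, and its standard error (SE) is the fold change over the square root of the F statistic. Group values of tested genes are mean ± SD of TMM-scaled CPM (counts per 1e6 counts), while marker and sex-linked transcripts, and levels of single libraries, are given in plain CPM. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

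The difference of the sire effect between regions was tested with an edgeR quasi-likelihood contrast over all 24 libraries, with 4 group means. The correlation across genes of the 2 sire effects was set against 100 draws of the sire labels within each region. Gene lists, 38 in all, covered 16 cell types a punch could hold and 22 functional groups. In each region 37 of them had at least 5 tested members. They were tested against all other genes with limma's camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with adjustment over the 37 lists. The same lists were tested with an estimated correlation, with fry, and by an exact permutation test of the list's mean log2 CPM, called its score. The last 2 ask whether a list changed at all, while camera compares it with the other genes. The smallest p such a permutation test can give was 0.000583 for 7 against 7 and 0.00794 for 5 against 5. In each region 20 marker transcripts, the total count and the ribosomal share formed a family of 22 exact permutation tests, on log2(CPM + 1) for transcripts. Correlations across libraries between list scores formed a family of 5, with p from 100000 permutations.

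Named genes followed a rule. Where fewer than 10 genes passed in a region, the 10 with the smallest p, a mean of at least 1 CPM and a symbol were named. Oprm1, Oprk1, Oprd1, Penk, Pdyn, Drd1, Drd2, Th, Slc6a3, Bdnf and Fos were named in each region, as were up to 4 members of smallest p of each called list and the 6 genes of smallest interaction p. The groups, comparisons, tests of genes and of lists by camera, the lists and this rule were chosen before the data were examined. Region markers were then to be described without a test. The permutation tests of marker transcripts were added to that plan later. Other genes named in the text were chosen after their values were seen.

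Alternatives covered DESeq2, limma-voom with sample quality weights, RLE, upper-quartile and total-count scaling, no filter and a stricter filter, the replicate number as a block, 1 surrogate variable, marker scores as covariates, a threshold of 0.1, and leaving out each library in turn. Further alternatives were chosen after seeing the data: DESeq2 on the genes kept by edgeR's filter, fits without the 4 VTA libraries above 10 CPM of Xist or with that status as a covariate, the serotonin neuron score, the depth class (30 M) or the library number class (above 8 in NAC, above 30 in VTA) as a covariate, fits without the 3 NAC libraries of lowest striatal score, the permutation tests of list scores, and protein-coding genes with a symbol as the background of the list test. The scripts were tested on simulated data drawn from the real means, dispersions and library sizes, each gene independently of the others. Variation shared between genes, such as that of punch content, was left out, so recovery in the real data may be lower. Changed genes were drawn only from those with a mean of at least 1 CPM, so recovery of lower genes is not covered. In NAC, 60 of 100 genes changed 1.5-fold and 91 of 100 changed 2-fold were called, with 3 false calls among 18220 genes. In VTA the corresponding numbers were 49 and 72 of 100, with 2 false calls among 19923 genes. No pair of libraries in a group held identical values or differed by less than sampling noise. The lowest chi-square per degree of freedom of any pair was 14.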

Results

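Transcript levels were measured by RNA sequencing in tissue punches of the nucleus accumbens (NAC) and the ventral tegmental area (VTA) of adult offspring of rats that had self-administered morphine or saline for 60 days. The NAC is a striatal region that receives dopamine, and the VTA holds dopamine neurons that project to it. NAC was represented by 7 SAL-sired and 7 MOR-sired libraries, and VTA by 5 and 5. Total estimated counts were 28.5 ± 6.13 M in SAL-sired NAC, 25.9 ± 2.89 M in MOR-sired NAC, 33.8 ± 7.57 M in SAL-sired VTA and 34.4 ± 8.54 M in MOR-sired VTA (SD, 1 M being 1e6 counts). Between 24664 and 26962 of the 37403 genes had at least 1 count in a library.

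The punches differed between regions in the transcripts of their main neurons. Th, which encodes the rate-limiting enzyme of dopamine synthesis, averaged 2116 ± 597 CPM in VTA (SD, n = 10) and 1.22 ± 0.348 CPM in NAC (n = 14). The dopamine transporter Slc6a3 averaged 1514 ± 413 CPM in VTA and 0.347 ± 0.188 CPM in NAC. Drd1, the dopamine receptor of direct-pathway striatal neurons, averaged 98.8 ± 68.4 CPM in NAC and 1.47 ± 0.174 CPM in VTA. The 2 tables were deposited separately, so these levels were not tested against each other.

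NAC punches also differed widely from each other in striatal and cortical transcripts. Adora2a, the adenosine receptor of indirect-pathway striatal neurons, ranged from 61.4 to 288 CPM in SAL-sired NAC and from 3.97 to 335 CPM in MOR-sired NAC. Ppp1r1b, which encodes DARPP-32, ranged from 160 to 3119 CPM over the 14 libraries. Slc17a7, the vesicular glutamate transporter of cortical neurons, ranged from 111 to 1366 CPM. Across the 14 libraries the striatal list score fell as the cortical glutamatergic score rose, with r = −0.676 (permutation p = 0.0042, adjusted p = 0.01 over a family of 5) and rho = −0.82 (permutation p = 6e-04, adjusted p = 0.003). Without MOR-sired NAC 2 and 7, the libraries farthest from the median, r was −0.774, and within groups it was −0.939 in SAL-sired and −0.789 in MOR-sired NAC. The striatal and oligodendrocyte scores gave r = −0.563 (permutation p = 0.036, adjusted p = 0.045) and rho = −0.486 (permutation p = 0.082, adjusted p = 0.14), and r was −0.325 without the same pair of libraries, −0.323 in SAL-sired and −0.747 in MOR-sired NAC. The sire groups did not pass a test for Adora2a (exact permutation p = 0.251, adjusted p = 0.747 over 22 tests) or the striatal score (6.64 ± 0.659 in SAL-sired and 6.03 ± 1.45 in MOR-sired NAC, exact permutation p = 0.334).

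**Figure D1:**
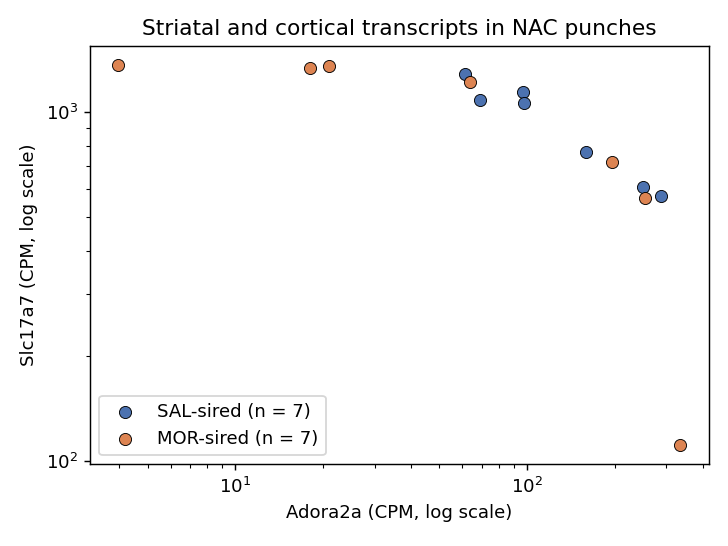
Adora2a (horizontal) against Slc17a7 (vertical) in NAC, in CPM on log scales; each point is 1 library, blue for SAL-sired and orange for MOR-sired (n = 7 each). Adora2a runs from 3.97 to 335 CPM and Slc17a7 from 111 to 1366 CPM, and libraries high in one are low in the other.

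The offspring are described as male, and sex-linked transcripts were read in each library. In 20 of the 24 libraries Xist, the transcript of the inactive X chromosome, lay between 0 and 0.245 CPM, and the Y-linked Ddx3y lay between 28.7 and 57.5 CPM. In the other 4 libraries, all from VTA (MOR-sired VTA 3, 4 and 5 and SAL-sired VTA 5), Xist lay between 78.9 and 108 CPM. In those 4 libraries Ddx3y reached at most 0.0762 CPM, Eif2s3y at most 0.305 CPM, and Kdm5d and Uty at most 0.027 CPM. The libraries labelled male thus differed in sex-linked transcripts, unequally between the sire groups (3 of 5 MOR-sired and 1 of 5 SAL-sired VTA libraries). VTA counts are therefore also given without these 4 libraries. That leaves SAL-sired VTA 1, 2, 3 and 4 against only MOR-sired VTA 1 and 2, so such fits have less power.

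**Figure D2:**
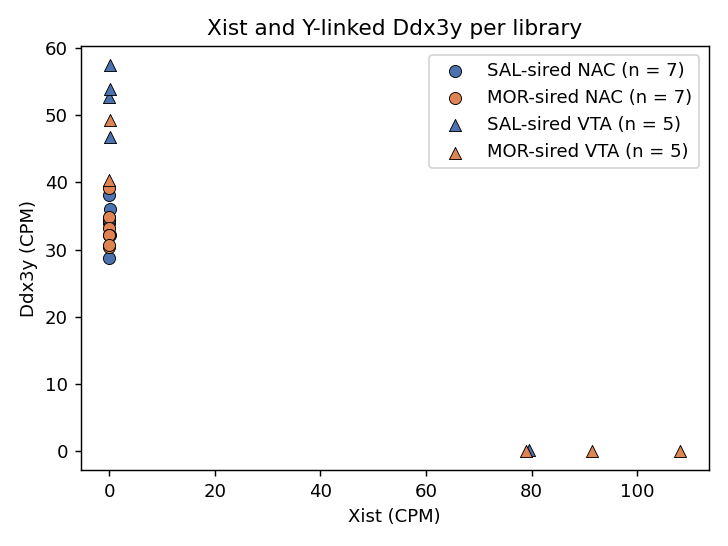
Xist (horizontal) against Ddx3y (vertical), both in CPM, in the 24 libraries; circles are NAC, triangles VTA, blue SAL-sired and orange MOR-sired. At the right, 4 VTA libraries have 78.9 to 108 CPM of Xist and at most 0.0762 CPM of Ddx3y, and the other 20 libraries lie at the left with 28.7 to 57.5 CPM of Ddx3y.

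The first comparison asked whether transcript levels in the NAC differed between offspring of morphine- and saline-exposed fathers. No single gene separated the groups beyond adjustment, and the named genes of smallest p differed by at most 1.42-fold. Aqp4, the water channel of astrocyte endfeet, averaged 151 ± 14.5 CPM in SAL-sired and 123 ± 10.0 CPM in MOR-sired NAC (SD, n = 7 each), a fold of 0.816 with a 95% interval of 0.745 to 0.895. Glt8d1, a glycosyltransferase-domain gene, averaged 24.4 ± 1.80 and 32.8 ± 4.71 CPM (fold 1.34, 1.19 to 1.51), and each of the 7 MOR-sired libraries lay above every SAL-sired one. edgeR's quasi-likelihood test called 0 of 18220 genes (smallest adjusted p = 0.56). At an unadjusted p under 0.05 it gave 1126 genes, 800 of them higher and 326 lower in MOR-sired NAC. Evenly spread p-values would give 911, but other random splits of the same libraries gave from 166 to 4207. The 1126 lie inside that range, so an excess over chance was not shown. Such a range does not tell how the 1126 compare with a typical split. DESeq2 called 73 genes, 46 of them detected in at most 2 libraries and 48 of them small RNAs, and 4 genes when given the genes that edgeR's filter kept (Glt8d1, Haghl, Tmem176a and 1 LOC identifier). limma-voom with sample quality weights called 52, of which 49 were LOC genes with identical values and only Haghl and Tmem176a had symbols.

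The other named genes of smallest p in NAC did not pass either. Higher means in MOR-sired NAC were found for Haghl (19.1 ± 0.845 against 24.6 ± 2.92 CPM, log2 fold change 0.37, SE 0.07), Lmbr1l (0.40, SE 0.09), Ppil6, a peptidyl-prolyl isomerase family member (0.51, SE 0.12), Csf2ra, the GM-CSF receptor alpha chain (0.39, SE 0.09), and Cdc23, a subunit of the anaphase-promoting complex (0.16, SE 0.04). Lower means were found for Tmem176a (76.2 ± 3.82 against 66.4 ± 2.39 CPM, −0.20, SE 0.04), Usp53, of the ubiquitin-specific protease family (−0.28, SE 0.06), and Laptm5, a lysosomal membrane protein of microglia and blood cells (−0.17, SE 0.04). Each had an adjusted p of 0.56 by edgeR.

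Opioid and dopamine genes were fixed in advance and none passed in NAC. The mu opioid receptor Oprm1 averaged 6.70 ± 2.02 CPM in SAL-sired and 4.94 ± 2.64 CPM in MOR-sired NAC (fold 0.738, 95% interval 0.474 to 1.15). The kappa and delta receptors Oprk1 and Oprd1 had log2 fold changes of −0.19 (SE 0.40) and −0.05 (SE 0.12). Their peptide precursors Penk (733 ± 415 against 731 ± 669 CPM) and Pdyn (182 ± 101 against 181 ± 171 CPM) had nearly equal means with a large spread. Drd1 (−0.05, SE 0.54), Drd2 (−0.24, SE 0.62), Th (−0.06, SE 0.23), Bdnf (0.12, SE 0.44) and Fos (−0.10, SE 0.21) also lay within their errors. Slc6a3 was too low in NAC to be kept by edgeR's filter, and did not pass as a marker (exact permutation p = 0.0839, adjusted p = 0.747 over 22 tests).

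Of 37 gene lists, 16 were called in NAC by camera with the preset correlation, and each of the 16 was lower in MOR-sired NAC against all other genes. With an estimated correlation 0 were called (smallest adjusted p = 0.381 with an estimated correlation), fry called 0 (smallest adjusted p = 0.308) and the exact permutation test of list scores called 0 (smallest adjusted p = 0.25), with 6 lists at an unadjusted permutation p under 0.05. Unlike camera, fry and the permutation test ask whether a list changed at all, not whether it changed more than other genes. With a covariate for the library number (1 to 8 or 9 to 14), chosen after seeing the data, 11 lists were called, 10 of them among the 16. Against protein-coding genes with a symbol as the background, chosen after seeing the data, 12 lists were called, and all 12 were among the 16. Over all genes 0 members passed, and 5 were called when adjusted over the list alone: Aqp4 (astrocyte), Laptm5 and Csf1r (microglia), Mia (ependymal cilia) and Hdac3 (DNA methylation and histone modifying enzymes). Mia and Hdac3, named after their values were seen, were higher in MOR-sired NAC, with log2 fold changes of 0.85 (SE 0.23) and 0.14 (SE 0.03).

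Vascular and glial lists were among the 16. Of 16 mural cell and fibroblast genes, 14 had lower means in MOR-sired NAC (adjusted p = 0.000407), among them the pericyte gene Rgs5 (136 ± 5.56 against 121 ± 11.8 CPM) and the fibrillar collagens Col1a1, Col1a2 and Col3a1 (log2 fold changes of −0.54, −0.55 and −0.54). The call was kept without any single library, but the score difference of −0.214 became −0.11 without SAL-sired NAC 7, which was highest in this list. For endothelial cells 15 of 18 were lower (adjusted p = 0.00184), among them the VEGF receptor Flt1 (−0.13), Vwf (−0.25), the receptor phosphatase Ptprb (−0.19) and VE-cadherin Cdh5 (−0.21). These lists each had an adjusted p = 0.381 with an estimated correlation. For microglia 16 of 19 were lower (adjusted p = 0.00908, and adjusted p = 0.381 with an estimated correlation), with Csf1r at 62.3 ± 3.31 against 55.8 ± 3.37 CPM and Trem2 at −0.13, while Cd68 was at 0.25. For astrocytes 15 of 18 were lower (adjusted p = 0.0162, and adjusted p = 0.492 with an estimated correlation), among them Aqp4, the glutamate transporter Slc1a2 (618 ± 42.9 against 549 ± 50.1 CPM), Fgfr3 (−0.10) and S100b (−0.07). For choroid plexus each of 10 tested genes was lower (adjusted p = 0.048, and adjusted p = 0.659 with an estimated correlation), including Otx2 (−0.73), Aqp1 (−1.01), Sostdc1 (−1.36) and Prlr (−0.52), all near or under 1 CPM. The astrocyte call was lost without SAL-sired NAC 4 or 5 or MOR-sired NAC 3 or 4 (adjusted p from 0.0529 to 0.144), the microglia call without MOR-sired NAC 1 or 3 (0.0703 and 0.0612), and the choroid plexus call without any one of SAL-sired NAC 4, 6 and 7 and MOR-sired NAC 1, 2, 3, 4 and 7 (0.0508 to 0.414).

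Neuronal and signalling lists made up most of the rest. For striatal medium spiny neurons 22 of 23 genes were lower (adjusted p = 0.00184, and adjusted p = 0.705 with an estimated correlation), including Ppp1r16b (−0.21), Rasd2 (−0.24), the transcription factors Foxp1 (−0.16) and Isl1 (−0.37). Without MOR-sired NAC 2 or 7 its adjusted p was 0.0961 or 0.0745. Of dopamine receptor and cAMP genes 31 of 34 were lower (adjusted p = 0.00184), among them Maoa (61.1 ± 5.13 against 54.7 ± 2.40 CPM), Atf2 (−0.14), Creb1 (−0.15) and Prkar1a (−0.10). For the opioid system 25 of 30 were lower (adjusted p = 0.00832), among them the kinase Grk5 (−0.14), beta-arrestin 1 Arrb1 (−0.10) and the processing enzyme Cpe (−0.08). For the GABA system 26 of 29 were lower (adjusted p = 0.00388), among them GABA transaminase Abat (−0.33), Kctd16 (−0.21), Gabrb2 (−0.18) and Gabra3 (−0.18). These 3 lists each had an adjusted p = 0.381 with an estimated correlation. With the striatal score as a covariate, chosen after seeing the data, the dopamine and cAMP list (adjusted p = 0.109) and the GABA list (0.112) were no longer called, and the opioid list was not called without MOR-sired NAC 4 (0.0793).

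Further called lists covered synapse, guidance and matrix genes. Lower means were found for 36 of 48 axon guidance genes (adjusted p = 0.00373), such as Slit2 (−0.26), Sema3c (−0.32), Sema5a (−0.20) and Sema3d (−0.26), and for 27 of 42 neuropeptides and receptors (0.00505), such as Adcyap1r1 (−0.07), Trh (−0.22), Npy1r (−0.26) and Trhr (−0.32). They were also found for 20 of 31 perineuronal net and matrix genes (0.00578), such as Adamts1 (−0.29), Sparc (485 ± 34.6 against 428 ± 23.0 CPM) and Timp2 (−0.19), and for 33 of 49 glutamate receptor and scaffold genes (0.0225), such as Grm3 (−0.22), Grin2b (−0.27) and Grid1 (−0.10). Those 4 lists each had an adjusted p = 0.381 with an estimated correlation. Of presynaptic release genes 35 of 46 were lower (adjusted p = 0.00505, and adjusted p = 0.659 with an estimated correlation), such as Rab3b (−0.16), Pclo (−0.14) and Syt2 (−0.29). Of potassium, HCN and calcium channels 32 of 45 were lower (adjusted p = 0.0463, and adjusted p = 0.511 with an estimated correlation), such as Kcnq3 (−0.17), Kcnj10 (−0.17) and Kcnj5 (−0.18), with Cacna1d at 0.09. Of cytosolic ribosomal proteins 57 of 76 were lower (adjusted p = 0.0248, and adjusted p = 0.823 with an estimated correlation), such as Rpl12 (−0.17), Rps28 (−0.08) and Rpl3 (−0.09), with Rps23 at 0.24. Leaving out MOR-sired NAC 4 left 7 called lists and ended the calls of the axon guidance (adjusted p = 0.201), neuropeptide (0.144), matrix (0.232), glutamate (0.106), presynaptic (0.472) and channel (0.314) lists. Calls were also lost for the glutamate list without SAL-sired NAC 2 or 3 or MOR-sired NAC 7 (0.0502 to 0.0831), for the presynaptic list without MOR-sired NAC 6 (0.0518), for the channel list without SAL-sired NAC 1, 2, 3 or 4 or MOR-sired NAC 6 or 7 (0.0593 to 0.197), and for the ribosomal list without SAL-sired NAC 4, 5 or 6 or MOR-sired NAC 1, 2, 3 or 5 (0.0685 to 0.796).

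The other 21 lists were not called in NAC. By camera, adjusted p was 0.082 for interneurons, 0.121 for the nuclear-encoded respiratory chain, 0.123 for subcortical and 0.132 for cortical glutamatergic neurons, 0.134 for neurotrophin signalling, 0.142 for immediate early genes, 0.153 for oligodendrocytes and 0.222 for inflammatory cytokines. It was 0.25 for midbrain GABA neurons, 0.377 for ependymal cilia and for interferon genes, 0.508 for dopamine neurons, serotonin neurons and the endocannabinoid system, 0.511 for oligodendrocyte precursors and 0.63 for collagens. It was 0.801 for glucocorticoid response genes, 0.882 for heat shock, DNA methylation and histone, and circadian clock genes, and 0.922 for blood. The median, mean and tested direction differed in sign for the collagen, endocannabinoid and heat shock lists.

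The second comparison asked the same question in the VTA. No single gene passed there either, but several showed larger differences than in NAC, with each of 5 MOR-sired libraries beyond every SAL-sired one. Cited1, a transcriptional coactivator gene, averaged 5.71 ± 0.996 CPM in SAL-sired and 11.4 ± 1.16 CPM in MOR-sired VTA (SD, n = 5 each), a fold of 1.99 with a 95% interval of 1.67 to 2.36. Gchfr, the regulatory protein of GTP cyclohydrolase, averaged 18.4 ± 5.86 and 43.9 ± 14.3 CPM (fold 2.39, 1.66 to 3.43), and Stk32b, a serine/threonine kinase gene, 3.95 ± 0.713 and 7.22 ± 1.36 CPM (fold 1.82, 1.47 to 2.27). edgeR's quasi-likelihood test called 0 of 19923 genes (smallest adjusted p = 0.223, for Cited1). At an unadjusted p under 0.05 it gave 1058 genes, 547 higher and 511 lower. Evenly spread p-values would give 996, and other random splits of the same libraries gave from 282 to 3110. DESeq2 called 115 genes, 52 of them detected in at most 2 libraries and 61 of them small RNAs, and 30 genes when given the genes that edgeR's filter kept. limma-voom with sample quality weights called 0, and edgeR called 0 also without the 4 libraries with Xist (smallest adjusted p = 0.0911).

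**Figure D3:**
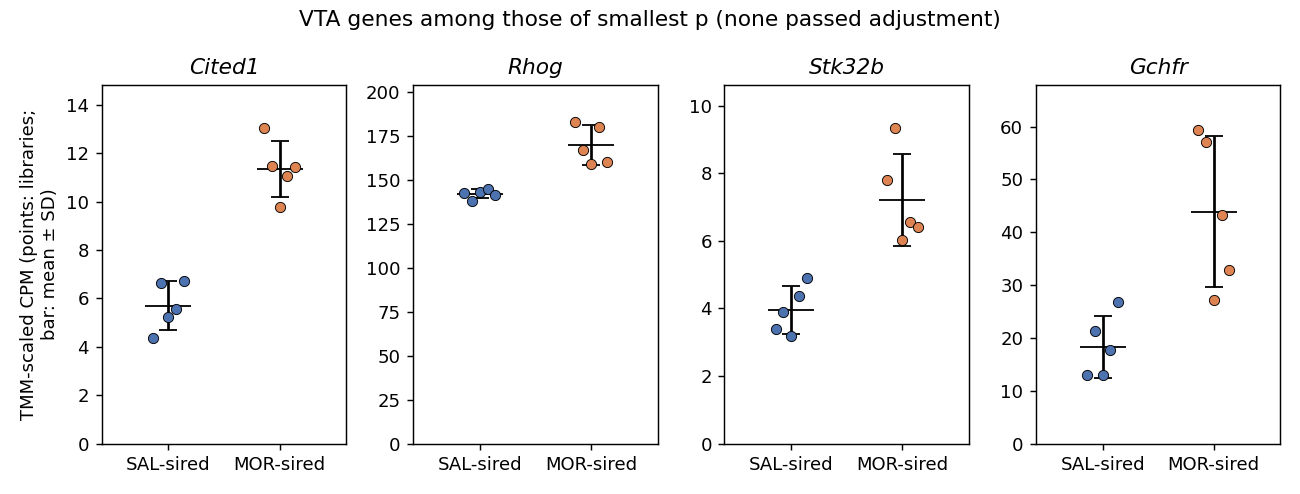
TMM-scaled CPM of Cited1, Rhog, Stk32b and Gchfr in VTA; points are libraries (n = 5 per group, blue SAL-sired, orange MOR-sired) and bars are mean ± SD. In each panel the 5 MOR-sired libraries lie above the SAL-sired ones, and none of the 4 genes passed adjustment.

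Among the other VTA genes of smallest p, each at an adjusted p of 0.793 by edgeR, higher means in MOR-sired VTA were found for the small GTPase Rhog (142 ± 2.51 against 170 ± 11.2 CPM, log2 fold change 0.26, SE 0.05), the focal adhesion gene Zyx (0.25, SE 0.05), the glutathione transferase Gstm6 (0.50, SE 0.10) and Gata2, a transcription factor of midbrain GABA neurons (4.86 ± 0.681 against 7.76 ± 1.44 CPM, 0.67, SE 0.14). Lower means were found for Rflna (−0.67, SE 0.13), Arpp21, a cAMP-regulated phosphoprotein gene (34.9 ± 16.6 against 13.4 ± 2.88 CPM, −1.37, SE 0.29), and H3f3a-ps9 (−2.44, SE 0.49), a pseudogene whose reads are shared with near-identical histone genes and whose level is uncertain. DESeq2 on the genes kept by edgeR's filter called each of these 7 genes, Cited1, Stk32b and Gchfr.

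None of the opioid and dopamine genes fixed in advance passed in VTA. Penk averaged 34.1 ± 11.6 CPM in SAL-sired and 47.3 ± 11.7 CPM in MOR-sired VTA (fold 1.38, 95% interval 1.01 to 1.90, adjusted p = 0.953 by edgeR). Oprm1 (3.41 ± 1.25 against 3.46 ± 0.221 CPM), Oprk1 (log2 fold change 0.09, SE 0.16), Oprd1 (−0.33, SE 0.42) and Pdyn (0.03, SE 0.32) lay within their errors. Th averaged 1895 ± 656 and 2342 ± 499 CPM (0.31, SE 0.23), Slc6a3 1433 ± 499 and 1599 ± 332 CPM (0.16, SE 0.24), and Drd2 124 ± 43.7 and 146 ± 25.1 CPM (0.24, SE 0.22). Drd1 (0.04, SE 0.14), Bdnf (−0.14, SE 0.13) and Fos (−0.13, SE 0.27) did not separate the groups.

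Serotonin and midbrain GABA neuron genes had higher means in MOR-sired VTA. Each of 9 serotonin neuron genes had a higher mean there (camera adjusted p = 5.07e-08, and adjusted p = 0.376 with an estimated correlation), and the list score was 1.99 ± 1.08 in SAL-sired and 3.74 ± 0.453 in MOR-sired VTA (n = 5 each, exact permutation p = 0.00794, the smallest possible, adjusted p = 0.294 over the lists). Tph2, the enzyme that makes serotonin in neurons, averaged 23.5 ± 25.9 CPM in SAL-sired and 115 ± 43.4 CPM in MOR-sired VTA, and the serotonin transporter Slc6a4 averaged 14.8 ± 15.8 and 71.1 ± 28.0 CPM (exact permutation p = 0.00794 and adjusted p = 0.0582 for each). The serotonin neuron transcription factor Fev averaged 1.26 ± 1.29 and 6.60 ± 3.08 CPM (exact permutation p = 0.0159, adjusted p = 0.0874). In the same family of 22 tests Adora2a went the other way, with 3.64 ± 0.596 CPM in SAL-sired and 2.70 ± 0.137 CPM in MOR-sired VTA (exact permutation p = 0.00794, adjusted p = 0.0582). With 5 against 5 libraries this p is the smallest possible, too large for a single transcript to pass over 22 tests. That Tph2, Slc6a4 and Adora2a did not pass thus carries little weight. These marker tests were also not part of the plan fixed in advance. Over all genes 0 members of the serotonin list passed, and 4 of 9 were called when adjusted over the list alone: Htr5b (log2 fold change 2.08, SE 0.46), Fev (fold 5.66, 95% interval 2.10 to 15.2), Gata3 (0.68, SE 0.24) and the monoamine transporter Slc22a3 (1.01, SE 0.37). Each of 12 midbrain GABA neuron genes had a higher mean too (adjusted p = 5.07e-08, and adjusted p = 0.376 with an estimated correlation), among them Sox14 (0.83, SE 0.30) and Pax7 (1.01, SE 0.41), and Gata2 was called over the list alone. Gata3 also stands in the midbrain GABA list and Lmx1b in the dopamine neuron list. Single libraries of SAL-sired VTA ranged from 0.337 to 56.1 CPM of Tph2 and those of MOR-sired VTA from 59.7 to 156 CPM.

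**Figure D4:**
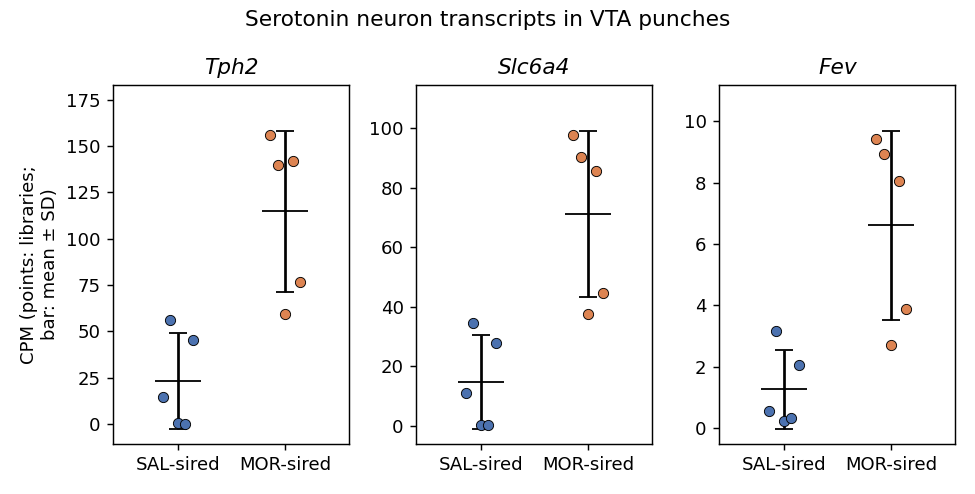
CPM of Tph2, Slc6a4 and Fev in VTA; points are libraries (n = 5 per group, blue SAL-sired, orange MOR-sired) and bars are mean ± SD. Tph2 lies between 0.337 and 56.1 CPM in SAL-sired and between 59.7 and 156 CPM in MOR-sired libraries.

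The serotonin score also followed other cell type scores across the 10 VTA libraries, within the same family of 5 relations. With the midbrain GABA score r was 0.832 (permutation p = 0.0033, adjusted p = 0.01) and rho was 0.794 (permutation p = 0.0092, adjusted p = 0.023). With the subcortical glutamatergic score r was −0.672 (permutation p = 0.033, adjusted p = 0.045) and rho was −0.491 (permutation p = 0.15, adjusted p = 0.19), and with the dopamine neuron score r was 0.599 (permutation p = 0.068, adjusted p = 0.068) and rho 0.248 (permutation p = 0.49, adjusted p = 0.49). Without SAL-sired VTA 3 and 4, which were lowest in serotonin transcripts, r was 0.468, −0.0351 and −0.335 in that order (GABA, glutamatergic, dopamine). Within SAL-sired VTA r was 0.826, −0.797 and 0.779, and within MOR-sired VTA it was −0.0583, −0.853 and −0.458, so only the glutamatergic relation had the same sign in both groups. With the serotonin score as a covariate, chosen after seeing the data, 5 lists were called, the GABA neuron list was not (adjusted p = 0.714), and 3 of the 10 lists called without it were shared. Each MOR-sired VTA library scored above every SAL-sired one (exact permutation p = 0.00794), so this covariate overlaps with sire. Calls lost in this fit therefore cannot tell serotonin content from sire.

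Of 37 lists, 10 were called in VTA by camera with the preset correlation, 6 higher and 4 lower in MOR-sired VTA, and 7 members were called when adjusted over the list alone. With an estimated correlation 0 were called (smallest adjusted p = 0.376 with an estimated correlation), as with fry (smallest adjusted p = 0.218) and the exact permutation test of list scores (smallest adjusted p = 0.294), with 2 lists at an unadjusted permutation p under 0.05. With 5 against 5 libraries the smallest possible p, 0.00794, is too large for a single list to pass that test over 37 lists, so its 0 carries little weight. Each list below had an adjusted p = 0.87 with an estimated correlation. Of oligodendrocyte and myelin genes 19 of 22 were higher (adjusted p = 0.000665), among them Sox10 (99.2 ± 4.85 against 115 ± 5.20 CPM, called over the list alone), Myrf (log2 fold change 0.18), Hapln2 (0.24) and Mag (0.20). Of dopamine neuron genes 17 of 20 were higher (adjusted p = 0.00278), such as GTP cyclohydrolase Gch1 (85.5 ± 30.4 against 118 ± 11.5 CPM), En1 (0.34) and En2 (0.35). Of interferon and antigen presentation genes 30 of 34 were higher (adjusted p = 0.00278), such as Ifit3 (2.25 ± 0.173 against 3.77 ± 1.83 CPM), Ifi44l (0.52) and Ifit2 (0.34), and of microglia genes 17 of 19 (adjusted p = 0.0103), such as Tyrobp (35.7 ± 1.52 against 48.0 ± 7.18 CPM, called over the list alone), Cd74 (1.17, SE 0.64), P2ry13 (0.22) and Cx3cr1 (0.17).

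Lower lists in MOR-sired VTA were those of connective tissue, choroid plexus and immediate early genes, each with an adjusted p = 0.87 with an estimated correlation. Of collagen and basement membrane genes 29 of 37 were lower (adjusted p = 2.03e-05), among them Col6a2 (11.5 ± 4.66 against 5.20 ± 0.752 CPM), Col5a1 (−1.02), Col18a1 (−0.57) and Col1a2 (20.9 ± 22.0 against 5.55 ± 0.734 CPM), and the score difference of −0.304 became −0.176 without SAL-sired VTA 1. Of mural cell and fibroblast genes 13 of 16 were lower (adjusted p = 0.00291), such as smooth muscle myosin Myh11 (−0.44), Col1a1 (−1.34) and Slc6a13 (−1.54). Of choroid plexus genes 9 of 13 were lower (adjusted p = 0.0449), such as transthyretin Ttr (22.2 ± 18.1 against 4.07 ± 2.05 CPM), Kcnj13 (−1.74) and Sostdc1 (0.429 ± 0.261 against 0.224 ± 0.119 CPM), with Slc4a5 at 0.36. Of immediate early genes 32 of 44 were lower (adjusted p = 0.0449), such as Gadd45g (15.9 ± 2.27 against 12.5 ± 1.06 CPM), Egr3 (−2.90, SE 1.12) and Ier5 (−0.31), with Maff at 0.44.

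Several VTA list calls were lost without a single library or without the 4 libraries with Xist. Leaving out the 4 set only MOR-sired VTA 1 and 2 against SAL-sired VTA 1 to 4. A loss there can reflect lower power as well as dependence on the 4 libraries. Without those 4, 9 lists were called, 4 of them among the 10, and the dopamine neuron (adjusted p = 0.261), microglia (0.261), mural cell (0.445), choroid plexus (0.0589), immediate early (0.445) and interferon (0.904) lists were not. The interferon list turned to the lower side without MOR-sired VTA 3 (adjusted p = 0.865) and was not called without SAL-sired VTA 4 (0.0968). Calls were lost for dopamine neurons without SAL-sired VTA 3 or 4 or MOR-sired VTA 3 or 4 (0.0581 to 0.238), for microglia without SAL-sired VTA 3, 4 or 5 or MOR-sired VTA 4 (0.0657 to 0.134), for oligodendrocytes without MOR-sired VTA 1 (0.187) and for mural cells without SAL-sired VTA 1 or MOR-sired VTA 3 (0.0682 and 0.162). The choroid plexus and immediate early calls were each lost without any one of SAL-sired VTA 1, 2 and 4 and MOR-sired VTA 2, 3 and 5 (0.0639 to 0.279 and 0.0646 to 0.42). Leaving out SAL-sired VTA 4 left 6 called lists. The ribosomal share of counts was 13.5% in MOR-sired VTA 2 and 6.07% in MOR-sired VTA 4, against 0.141% to 0.492% in SAL-sired VTA (exact permutation p = 0.0397, adjusted p = 0.175 over 22 tests, n = 5 each).

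The other 27 lists were not called in VTA. Adjusted p by camera was 0.0601 for endothelial cells, for potassium, HCN and calcium channels and for neuropeptides, 0.128 for glutamate receptors and scaffold, 0.133 for cortical glutamatergic neurons, 0.255 for astrocytes, 0.264 for axon guidance, 0.29 for glucocorticoid response genes and 0.294 for the respiratory chain. It was 0.312 for blood and for ribosomal proteins, 0.464 for interneurons and the circadian clock, 0.63 for the perineuronal net, 0.643 for oligodendrocyte precursors, 0.679 for neurotrophin signalling and 0.69 for heat shock genes. It was 0.684 for striatal neurons and ependymal cilia, 0.735 for endocannabinoids, 0.917 for dopamine receptor and cAMP genes and for the GABA system, 0.938 for inflammatory cytokines, and 0.943 for subcortical glutamatergic neurons, the opioid system, presynaptic genes and DNA methylation and histone enzymes. The median, mean and tested direction differed in sign for the opioid, neurotrophin, heat shock, endocannabinoid, presynaptic and cytokine lists.

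The third comparison asked whether the sire effect differed between regions. Stk32b had the smallest p: its log2 fold change was −0.19 (SE 0.12) in NAC and 0.87 (SE 0.16) in VTA, a difference of 1.07 (SE 0.20). Cfap410 followed with −0.10 (SE 0.04) in NAC, 0.20 (SE 0.05) in VTA and a difference of 0.32 (SE 0.07). The other 4 were ribosomal or signal recognition particle transcripts, Rn45sl1, Rn5-8s, Rn28s and Rn7sl1, with differences of 2.66 (SE 0.58), 4.40 (SE 0.99), 4.21 (SE 0.96) and 4.78 (SE 1.09), and they were highest in the MOR-sired VTA libraries with a high ribosomal share. These transcripts come in near-identical copies, so their levels are uncertain. edgeR's quasi-likelihood test called 0 of 20603 genes (smallest adjusted p = 0.421). At an unadjusted p under 0.05 it gave 984 genes, where evenly spread p-values would give 1030 and other random splits gave from 381 to 2985. DESeq2 called 145 genes, 89 of them detected in at most 2 libraries of NAC or of VTA, and edgeR's filter kept 93 of the 145. The difference of the separate fold changes over its SE, set against a normal distribution, called 2 (Stk32b and Cfap410). Without the 4 libraries with Xist edgeR called 7 (Stk32b, Nr2e1, Rprml, Slc6a5, Dbndd2, Rn45sl1 and 1 LOC identifier).

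Sire effects in the 2 regions had a correlation near 0 across 17697 genes tested in both (r = −0.0177, rho = 0.0779; genes are not independent replicates). On log2 CPM differences r was −0.177, and 6 of 100 draws of the sire labels, the real one included, gave a value as far from 0 (permutation p = 0.06). At an unadjusted p under 0.05 in both regions, 21 genes were higher in both (21.2 for independent lists) and 13 lower in both (8.41 for independent lists). As 0 genes were called in NAC and 0 in VTA, no overlap of called genes could arise.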

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

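The tests of explanations in this part were chosen only after the result was seen, except the test on X-linked genes. Within groups of 5 or 7 libraries, 182 sets of values were searched for 1 library far from the others; 16 had one, where about 9 arise by chance.

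Xist in SAL-sired VTA 5 was 79.5 CPM, against 0 to 0.245 CPM in the other SAL-sired VTA libraries. In the same library Ddx3y was 0.0762 CPM (46.7 to 57.5 in the others), Kdm5d 0.0254 (14.0 to 16.9), Eif2s3y 0.305 (66.0 to 81.8) and Uty 0.0254 (4.62 to 6.08). MOR-sired VTA 3, 4 and 5 showed the same pattern. A mixture of RNA from males and females is argued against, since the 4 libraries held at most 0.288% of the Y-linked transcripts of the other VTA libraries (0.432 against a median of 150 CPM). Too little depth is argued against too, since at least 5570 Y-linked counts would be expected and at most 17 were seen. Tissue from female animals, through a wrong label or a swap with other samples, may explain the pattern: 4 of 4 X-linked genes that escape inactivation (Kdm6a, Kdm5c, Ddx3x, Eif2s3) were higher in each of the 4 libraries than in each of the other 6 (chance 0.476% per gene). No biological explanation was tested, since the labels give 1 sex.

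Striatal transcripts differed between NAC punches, with Adora2a from 3.97 to 335 CPM over the 14 libraries. Different shares of striatal and cortical tissue in the punches may explain this, since the striatal and cortical scores fell against each other within both sire groups (r = −0.939 in SAL-sired and −0.789 in MOR-sired NAC). Sire exposure cannot be told apart from punch content: the difference of the striatal score between groups had an exact permutation p of 0.334, with an interval of −1.92 to 0.706 that leaves room for a sizeable fall.

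Serotonin neuron transcripts had higher means in MOR-sired VTA, with Tph2 at 23.5 ± 25.9 against 115 ± 43.4 CPM (exact permutation p = 0.00794, adjusted p = 0.0582 over 22 tests). That p is the smallest possible, and no single transcript could pass with it, so not passing carries little weight. The serotonin neuron list was called by camera with the preset correlation (adjusted p = 5.07e-08) but not with an estimated correlation (adjusted p = 0.376) or fry (adjusted p = 0.218). The 4 libraries with Xist are argued against as the source, since without them the difference of Tph2 was 4.49 on the log2(CPM + 1) scale, against 3.47 with them. The value without them compares only MOR-sired VTA 1 and 2 with SAL-sired VTA 1 to 4. Different amounts of serotonin neuron tissue in the punches may explain the pattern: over 8 libraries Slc6a4 and Tph2 kept a nearly fixed ratio (SD 0.104 of the log2 ratio) while Tph2 varied with an SD of 1.13. Sire exposure cannot be told apart from this, as a different amount of tissue would move the score alike. The score had a higher mean in MOR-sired VTA (95% interval of the difference 0.539 to 2.95). Its exact permutation p of 0.00794 (adjusted p = 0.294 over the lists) is the smallest possible. No single list could pass with it, so not passing decides nothing.

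In MOR-sired NAC 4 the Y-linked Kdm5d was 17.7 CPM (12.7 to 13.4 in the others) and Uty 7.26 CPM (4.12 to 4.61), and the mean log2 CPM of the neuropeptide list was 3.45 (3.83 to 4.11). In SAL-sired NAC 3, Tmem176a was 68.2 CPM (75.3 to 79.6) and Oprd1, the delta opioid receptor, 16.3 CPM (9.37 to 11.8). The mural cell and fibroblast list stood at 4.13 in SAL-sired NAC 7 (3.31 to 3.49), Xist at 0.215 CPM in SAL-sired NAC 2 (0 to 0.0725), and the total count at 41.3 M in SAL-sired NAC 5 (21.9 to 29.1). In VTA, the kappa opioid receptor Oprk1 was 12.5 CPM in MOR-sired VTA 2 (16.1 to 17.1), the immediate early list 2.61 in MOR-sired VTA 1 (2.56 in the others), and the interferon list 3.8 in MOR-sired VTA 3 (2.39 to 2.64).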

How the results depend on the processing

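DESeq2 on the genes kept by edgeR's filter, the permutation of list scores, the covariates for serotonin, Xist and (for lists) the striatal or dopamine score, the protein-coding background, the depth and library number classes, and the fits without the Xist or lowest-striatal libraries were chosen only after seeing the data.

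By edgeR 0 genes were called in NAC, in VTA and for the interaction under RLE factors, no filter, a stricter filter, a threshold of 0.1 and each single library left out (0 to 0), beside 1126, 1058 and 984 genes at an unadjusted p under 0.05. DESeq2 called 73, 115 and 145 genes in these comparisons, of which edgeR's filter kept 16, 52 and 93. In NAC 46 and in VTA 52 of the called genes were detected in at most 2 libraries. For the interaction 89 were detected in at most 2 libraries of NAC or of VTA, which allows detection in the other region. On the genes that edgeR's filter kept DESeq2 called 4 in NAC and 30 in VTA, and limma-voom with sample quality weights called 52 in NAC and 0 in VTA; the cause was not tested. For the interaction, the difference of separate fold changes over its SE called 2, and edgeR without the 4 Xist libraries called 7. The cause was not tested. The first of these used a normal distribution, which tends to give smaller p-values with few libraries. Of the named genes DESeq2 called 9 in NAC and 19 in VTA. With the serotonin covariate 9 VTA genes, uncalled both ways, changed sign by at least their within-group SD (1 without the Xist libraries). The serotonin score separates the sire groups, so sign changes with that covariate decide nothing about these genes. Smaller sign changes were not counted.

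The 16 lists called in NAC and 10 in VTA fell to 0 in each region with an estimated correlation, with fry and with the permutation of list scores. The last 2 test against no change rather than against other genes, and in VTA no single list could pass the permutation test, given its smallest possible p of 0.00794. With the library number class as a covariate 11 lists were called in NAC (10 of the 16) and 14 in VTA (all 10 and 4 more). With the serotonin score as a covariate 5 lists were called in VTA, and 3 turned to the lower side: dopamine neurons (adjusted p = 0.0745), oligodendrocytes (0.868) and microglia (0.868). Since that score separates the sire groups, these losses and turns cannot tell serotonin content from sire. With the striatal score as a covariate 15 lists were called in NAC (10 of the 16; besides the striatal list, astrocyte, choroid plexus, dopamine and cAMP, GABA and ribosomal lists were lost, adjusted p from 0.0690 to 0.788). With the dopamine score 8 were called in VTA (7 of the 10; dopamine neuron, microglia and interferon lists lost, 0.192 to 0.927), and with Xist status 9 (5 of the 10; dopamine neuron, mural cell, choroid plexus, immediate early and interferon lists lost, 0.0576 to 0.919). Without the 3 libraries of lowest striatal score, all MOR-sired, 15 were called in NAC. They included 10 of the 16, of which 9 kept their direction and the striatal list turned. The striatal list turned to the higher side with its own score as a covariate (0.309) and without these 3 libraries (0.0105), but both settings condition on the value tested, so neither tells anything about that list; the same holds for the dopamine neuron list with its own score. Leaving out single libraries gave 7 lists (without MOR-sired NAC 4) to 17 (without SAL-sired NAC 3) in NAC and 6 (without SAL-sired VTA 4) to 12 (without SAL-sired VTA 5) in VTA. The VTA interferon list ranged from an adjusted p of 5.85e-05 without SAL-sired VTA 1 to 0.865 without MOR-sired VTA 3, where it turned to the lower side. The correlation of sire effects between regions ranged from −0.0635 (without SAL-sired VTA 2) to 0.0208 (without SAL-sired VTA 4).

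With the replicate number as a block 0 genes were called by edgeR in each comparison, and 15 lists in NAC and 10 in VTA (the channel list in NAC had an adjusted p of 0.0574). The values showed no clear pairing by number: correlations within pairs ran from −0.26 to 0.0964 in NAC and from −0.128 to 0.132 in VTA. The best match had the same number for 0 of 7 pairs in NAC and 2 of 5 in VTA. With so few pairs a weak pairing cannot be excluded. In simulated data of this depth and size, edgeR recovered 60 of 100 genes changed 1.5-fold and 91 of 100 changed 2-fold in NAC, and 49 and 72 in VTA. Changes under 1.5-fold, and changes in genes with a mean under 1 CPM, were not simulated. Variation shared between genes was not simulated either, so recovery in the real data may be lower.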

Other observations

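The tests on other splits of the samples (except that for long noncoding RNA, lncRNA), and those of library order and small RNAs for lncRNA, were chosen only after the results were seen.

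Some transcripts were high in few punches, and their source was not tested. Of the 10 VTA libraries, SAL-sired VTA 1 was highest in Ncmap (9.46 CPM), Wnt6 (8.55 CPM) and the organic anion transporter Slc22a6 (12.2 CPM), which was also 5.82 CPM in SAL-sired VTA 2 and 3.85 CPM in SAL-sired VTA 4, against a median of 0.602 CPM. Transthyretin, Ttr, the main transcript of choroid plexus, reached 828 CPM in SAL-sired NAC 7, with a second library at 783 CPM, a median of 12.1 CPM and a lowest value of 0.586 CPM. The neuropeptide galanin, Gal, averaged 3.02 ± 1.84 CPM in SAL-sired and 10.9 ± 5.29 CPM in MOR-sired VTA, and the glycine transporter Slc6a5 1.64 ± 0.981 and 6.03 ± 3.41 CPM (SD, n = 5 each; genes chosen after their values were seen).

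Interferon-induced genes were high in MOR-sired VTA 3. Mx1 stood at 12.6 CPM there, with 2.13 CPM in the next library, Irf7 at 17.0 CPM (next 6.60), Isg15 at 29.7 (12.7), Mx2 at 42.1 (18.3), Usp18 at 9.57 (4.09) and Rsad2 at 5.31 (1.61). The ribosomal transcript Rn28s was 36990 CPM in MOR-sired VTA 2 and 21420 CPM in MOR-sired VTA 4, against a median of 1642 CPM in VTA.

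Other splits of the same libraries were fitted like the real one. With the real split, edgeR called 0 genes in NAC, in VTA and for the interaction (1126, 1058 and 984 at an unadjusted p under 0.05, and 73, 115 and 145 by DESeq2), so 100 of 100, 100 of 100 and 60 of 60 splits necessarily gave as many, which says nothing about chance. The highest of the others called 2, 92 and 2 genes. At an unadjusted p under 0.05 by edgeR the other splits gave 166 to 4207, 282 to 3110 and 381 to 2985 genes. The real counts lie inside these ranges. The split with 92 genes set SAL-sired VTA 4 and 5 and MOR-sired VTA 3, 4 and 5 apart, which points to a structure of the samples. These are the 5 VTA libraries with the most counts (37.1 to 43.5 M, the others 23.6 to 36.7 M) and with library numbers 32 to 37 (the others 25 to 29), and they include all 4 with Xist. Xist alone does not account for the 92, since 5 other splits with all 4 on 1 side called 0 genes (3 splits) or 1 gene (2 splits). With the library number class as a covariate edgeR called 0 genes between sire groups in VTA (smallest adjusted p = 0.6). For gene lists, 6 of 100 splits gave as many as the real 16 in NAC (highest other 19) and 41 of 100 as many as the real 10 in VTA (highest other 17), so chance cannot be excluded for either count. Nor can it for the correlation of sire effects between regions on log2 CPM differences (real −0.177, 6 of 100 draws as far from 0, highest other 0.226).

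lncRNA genes had higher levels relative to protein-coding genes in MOR-sired NAC, a pattern noticed in the data. Their median log2 fold change was 0.17, with 73.9% of 2274 genes higher, against −0.01 and 44.8% of 14954 protein-coding genes with a symbol; in VTA it was 0.00, with 50.4% of 3229 higher. The shift in NAC was not particular to lncRNA: 63.4% of 415 protein-coding genes with LOC or RGD identifiers (median 0.08) and 66.4% of 577 genes of other classes (median 0.20) were higher too, and in VTA 62.2% of 670 genes of other classes (median 0.17) were. The lncRNA level of a library, on a log2 scale relative to protein-coding genes, was −3.78 ± 0.0551 in SAL-sired and −3.63 ± 0.135 in MOR-sired NAC (SD, n = 7 each). Only the real split, 1 of 100, gave a median difference as far from 0 (0.157, highest other 0.153), but the pattern was picked from the same data, so chance is not excluded for it. For library order, sire labels were exchanged only within libraries 1 to 8 and within 9 to 14 (exact permutation p = 0.00595 over 840 splits). The mean lncRNA level was higher in MOR-sired libraries within both classes, by 0.0718 and 0.155. That p carries the same choice from the data, and order within a class was not addressed, so library order is not excluded. A property of the libraries shared with small RNAs could explain it and cannot be told apart, as the shift followed the small RNA share in MOR-sired (r = 0.967) but less in SAL-sired NAC (r = 0.256); MOR-sired NAC 4, 5 and 6 were highest in both. Different shares of striatal and cortical tissue cannot be told apart either. Within groups the lncRNA level rose with the striatal score, but weakly (r = 0.293 in SAL-sired and 0.409 in MOR-sired NAC, n = 7 each). The mean striatal score was lower in MOR-sired NAC (6.03 against 6.64), so that relation would point to a lower lncRNA level there, not a higher one.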
